A study of Mus musculus with 9 samples.

How the data were processed

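RNA sequencing was done on 9 libraries of immortalised mouse embryonic fibroblasts, 3 of wild type cells, 3 of Ctr1-null cells and 3 of Ctr1-null cells given bathocuproine disulfonic acid (BCS) at 500 uM for 48 hours, per the labels (500 mM in the series record). The submitters' processing notes name FastQC, STAR, Salmon and DESeq2 and the build GRCm38, without versions or the role of each tool. The main table, as deposited by the authors, holds estimated counts per gene, rounded to whole numbers by the authors before deposit and not normalised. A further deposited table holds scaled signal values, which the authors made by dividing these counts by a factor for each gene and sample. Among 15225 genes with at least 10 counts in every sample these factors had a geometric mean of 1 within each gene, and how they were made is not stated. The tests used the counts, and the scaled table served only to recover the authors' factors for an alternative.

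Library totals were 47746926, 38962036 and 57206337 counts for wild type replicates 1, 2 and 3, 52306810, 50951927 and 47260223 for Ctr1-null and 53708329, 50738077 and 48368047 for Ctr1-null with BCS. A count of 0 allows up to 3 counts, which is 0.0524 to 0.0770 CPM in these libraries. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules. Standard errors and the 95% interval of a log2 fold change come from the edgeR fit and include the spread between libraries. Of 52661 gene rows, 52566 were matched by Ensembl identifier to a symbol in GENCODE M21 and 95 were not, and 17728 had no counts. The filter of edgeR (filterByExpr, minimum count 10, minimum total 15) left 18408 genes.

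Counts were scaled by TMM and tested in edgeR 4.0.16 (R 4.3.3) with a quasi-likelihood fit of all 9 libraries with 3 groups, which has 6 residual degrees of freedom and a common biological coefficient of variation of 0.169. The p-values were 2-sided and adjusted by Benjamini and Hochberg, with genes called at an adjusted p under 0.05. Standard errors are the log2 fold change divided by the square root of F. CPM values use the TMM-scaled totals. There were 35 pathway lists and 9 cell type lists, tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the pathway lists and over the cell type lists separately. Camera with a correlation estimated for each list and fry were run beside it. The groups, comparisons, lists, naming rule and most alternatives were fixed before the data were examined.

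Named genes were chosen by rule: Slc31a1, the 10 genes with the largest and the 10 with the smallest log2 fold change among those called, with at least 5 CPM in the higher group and no overlap between groups, leaving out predicted genes. The rule adds members of the copper transport list and, from each list, up to 2 called members in each direction or the member with the smallest p. Asns, Atf4, Bax, Ccdc13, Chac1, Fas, Gm45140, Herpud1, Ifit1, Isg15, Mcm7, Meg3, Msmo1, Pdgfra, Phlda3, Sqle, Trib3, Trp53, mt-Co1 and mt-Co3 fall outside it and were named after their values were seen. Genes first named under Other observations, among them Rian, Adipoq, Plin1, Cidec and Cfd, were also picked after the data were seen. Some other genes are named in a comparison where the rule names them only in another.

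Alternatives were DESeq2's size factors, upper-quartile factors or library size alone in edgeR, no filter or a stricter filter (at least 1 CPM in 3 samples), DESeq2 1.42.0, limma-voom, a fit of only the groups compared, a replicate block, a 2-fold threshold and leaving out each library in turn. The authors' factors in edgeR and in DESeq2 and a robust fit were added after the data were seen. The edgeR fit and camera were tested on simulated data for Ctr1-null against wild type, where 54 of 96 genes changed 2-fold and 84 of 100 changed 4-fold were recovered and 11 of 17837 unchanged genes were called. Camera gave an unadjusted p under 0.05 for 1 of 200 random lists there. Those genes were drawn independently, so this does not test camera on lists whose members vary together. In the data, the correlation estimated for nucleolar genes in Ctr1-null against wild type was 0.934. DESeq2, limma-voom and fry were not simulated. The comparison of the genotype and chelator changes used 100 simulated sets with shared Ctr1-null libraries, independently drawn genes and no effect. Trends on GC content and transcript length were fitted with mgcv 1.9.3. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No sample was left out. The value of 1 gene was left out of the text because it is withheld for evaluation.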

Results

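RNA was sequenced from mouse embryonic fibroblasts, a mixed connective-tissue cell culture, of C57BL/6 mice that had been immortalised with the T and t antigens of the SV40 virus. The cells either carried or lacked Ctr1, the high-affinity copper importer of the plasma membrane, whose gene is Slc31a1. A further group of Ctr1-null cells received bathocuproine disulfonic acid (BCS), a copper chelator that does not enter cells readily, at 500 uM for 48 hours according to the sample labels, whereas the series record gives 500 mM. Each of the 3 groups held 3 libraries, with totals from 38962036 to 57206337 counts per library. The deposited values were estimated counts per gene for 52661 gene rows, of which 18408 passed the filter on low counts and were tested. The labels do not state that the replicates came from separate cultures, so p-values of single genes measure only the spread between these libraries. Whether that spread is biological or technical is not known. Camera's p-values at the preset correlation of 0.01 compare list members with other genes and take the members as nearly independent. They do not measure the spread between libraries. Log2 fold changes are given ± their standard error unless stated.

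Slc31a1, the targeted gene (ENSMUSG00000066150.12, GRCm38 chromosome 4, 62360727 to 62391769, protein coding), had 55.2 ± 0.737 CPM (SD, n = 3) in wild type, 2.61 ± 1.24 CPM in Ctr1-null and 2.49 ± 0.774 CPM in Ctr1-null cells with BCS. The wild type libraries held 2697, 2026 and 2952 counts, the Ctr1-null libraries 128, 200 and 68, and the BCS libraries 178, 134 and 85. Ctr1-null cells were thus at 4.72% and BCS cells at 4.51% of the wild-type mean, and each library lay on the side its label gives. The log2 fold change against wild type was -4.40 ± 0.33 (SE) for Ctr1-null (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00303) and -4.47 ± 0.33 with BCS (adjusted p = 0.00135). BCS against Ctr1-null gave -0.07 ± 0.32 (adjusted p = 0.951), a difference within the spread between replicates. The counts are summed over the whole gene, so they include any reads from parts outside the deleted segment.

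**Figure D1:**
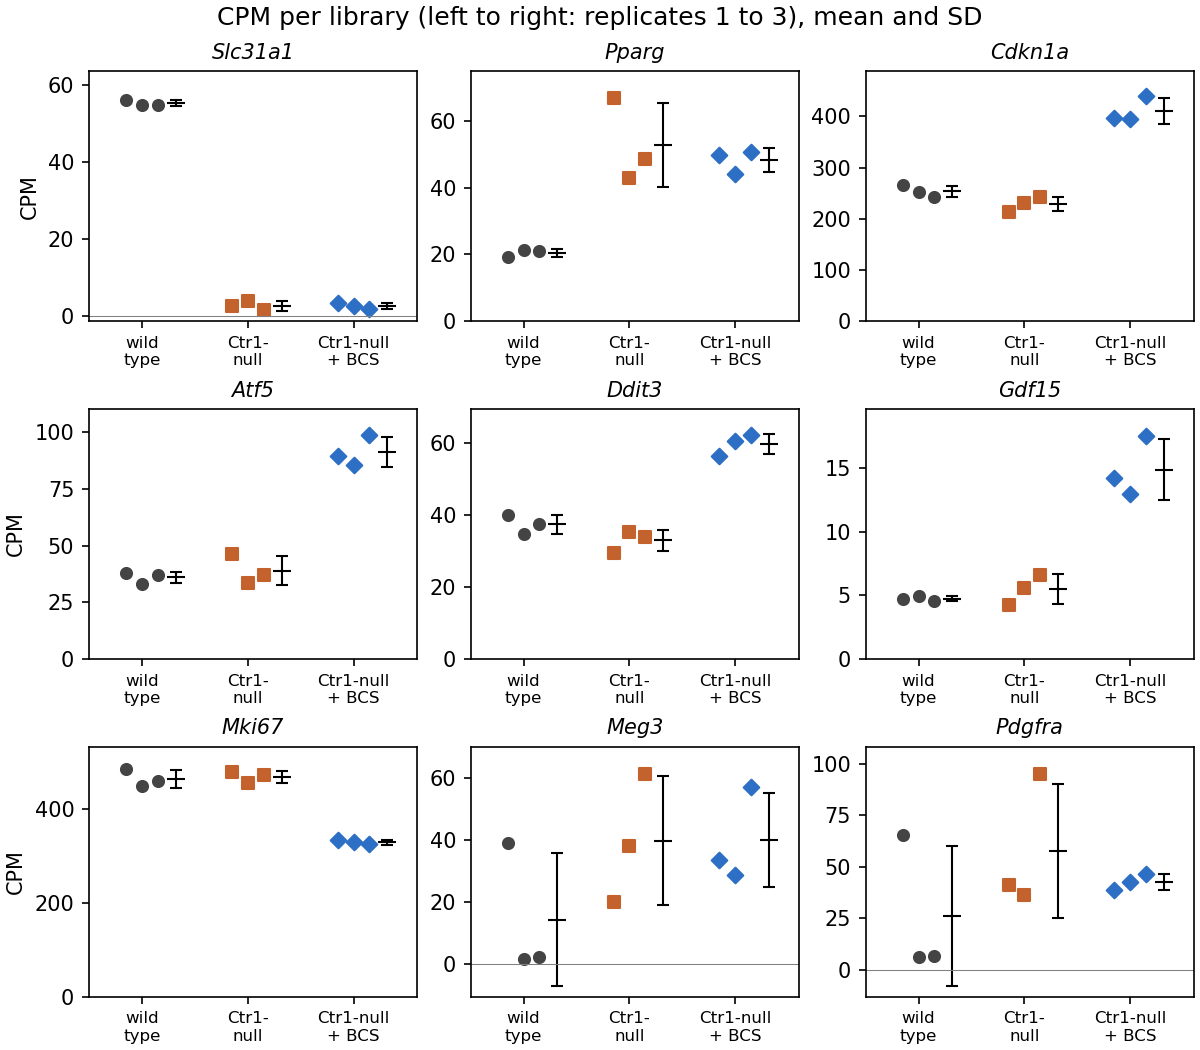
CPM of 9 genes in each of the 9 libraries, with 1 point per library (replicates 1 to 3 from left to right) and the group's mean and SD beside the points; each vertical axis has its own range and starts at or below 0. Slc31a1 is at 55.2 ± 0.737 CPM (SD) in the 3 wild type libraries against 2.61 ± 1.24 in Ctr1-null, Cdkn1a, Atf5, Ddit3 and Gdf15 are above both other groups in the 3 BCS libraries, and Meg3 and Pdgfra, picked after their values were seen, are high in wild type replicate 1 and low in replicates 2 and 3.

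The libraries of the wild-type group were not alike. On the first principal component, with 46.2% of the variance, wild type replicates 2 and 3 scored 67.1 and 63.3 and wild type replicate 1 scored -2.04, inside the Ctr1-null range of -32.0 to 9.05. Between wild type replicates 2 and 3, 676 genes differed by over 2-fold, against 2004 and 1817 between replicate 1 and these. Among the Ctr1-null libraries, replicate 1 differed from replicates 2 and 3 in 1087 and 1343 genes, against 756 between replicates 2 and 3. Meg3, a maternally expressed noncoding RNA, was at 38.9 CPM in wild type replicate 1 and at 1.59 and 2.04 in replicates 2 and 3, with 19.8, 37.8 and 61.3 in Ctr1-null. Pdgfra, a growth factor receptor of fibroblasts, was at 65.3, 6.11 and 6.62 CPM in wild type replicates 1, 2 and 3. Slc31a1 was at 56.1, 54.8 and 54.9 CPM in the same libraries. The number of genes called against wild type is therefore also given below without wild type replicate 1, while other counts against wild type include it.

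**Figure D2:**
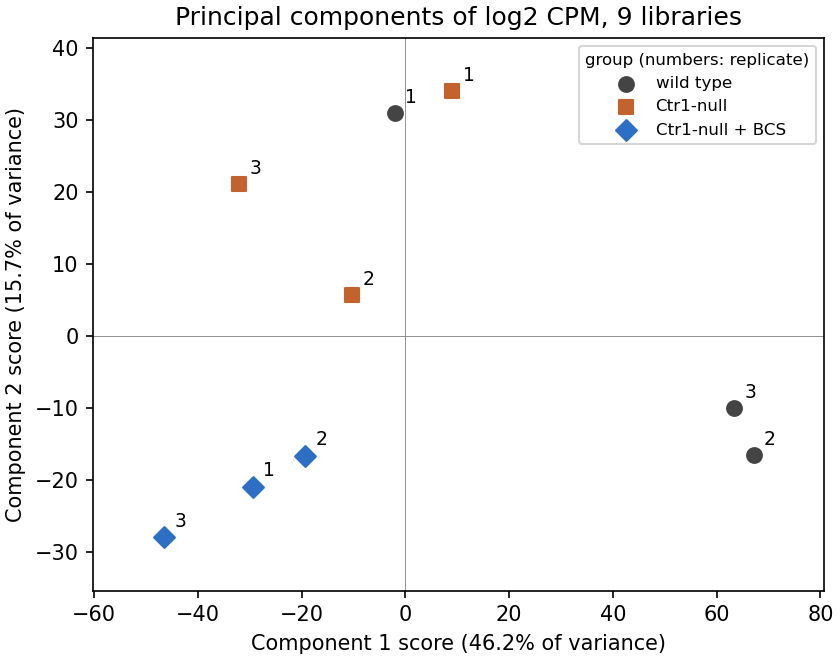
Scores of the 9 libraries on the first principal component (horizontal, 46.2% of variance) and the second (vertical, 15.7%) of log2 CPM, with the replicate number beside each point and the group as shape and colour. Wild type replicates 2 and 3 lie at 67.1 and 63.3 on the first component, and wild type replicate 1 lies at -2.04 among the Ctr1-null libraries.

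Ctr1-null against wild type compares cells without and with the copper importer. The labels do not state that the replicates came from separate cultures. Loss of Ctr1 therefore cannot be told apart from a difference between the cells in line, passage or origin. Pparg, the transcription factor that drives fat cell formation, was 20.5 ± 1.21 CPM (SD, n = 3) in wild type and 52.8 ± 12.5 CPM in Ctr1-null cells (GRCm38 chromosome 6, 115360951 to 115490399), a log2 fold change of 1.37 ± 0.15 (SE, edgeR adjusted p = 0.0451), higher in 3 of 3 libraries. Fabp4, a fatty acid binding protein under its control, had 2.06 ± 0.29 (adjusted p = 0.0592) and Cebpa, its partner factor, 1.84 ± 0.67 (adjusted p = 0.214). Cxcl10, an interferon-induced chemokine, had -2.94 ± 0.46 (adjusted p = 0.0707), Nnat, an imprinted membrane protein, -0.98 ± 0.14 (adjusted p = 0.0592), and Loxl2, a copper-dependent lysyl oxidase, -1.21 ± 0.28 (adjusted p = 0.110). Slc31a1 and Pparg were the only genes called among 18408, 1 in each direction. At an unadjusted p under 0.05 were 3239 genes, and 18.1% had groups that did not overlap, where chance gives 10% on average. Genes are not independent, so a single split can exceed that average. Setting wild type replicate 1 and Ctr1-null replicates 2 and 3 against the rest gave 5831 genes at an unadjusted p under 0.05 and 2349 called. The 3239 genes therefore do not set genotype apart. Without wild type replicate 1 the test called 3254 genes, 1737 higher and 1517 lower, with 6325 at an unadjusted p under 0.05, and DESeq2 on all 9 libraries called 1056. Wild type replicate 1 was left out because it differs from replicates 2 and 3, which narrows the wild type spread. The count of 3254 is therefore not a corrected measure of the genotype change. Pparg lost its call without wild type replicate 2 or 3, without Ctr1-null replicate 3 and without any 1 BCS library, each of which left 1 called gene. Its adjusted p was 0.266, 0.310 and 0.143 without the first 3, and 0.135, 0.0518 and 0.0620 without BCS replicates 1, 2 and 3.

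Of the 27 measured genes of copper transport and delivery, Slc31a1 alone fell over all genes tested and 2 fell adjusted over the list alone, the other being Slc11a2, a divalent metal transporter (-0.36 ± 0.09, adjusted p = 0.0499 over the list alone). The exporter Atp7a had -0.28 ± 0.08 (adjusted p = 0.151), the chaperones Atox1 and Ccs 0.04 ± 0.08 and -0.23 ± 0.12, and the low-affinity importer Slc31a2 -0.09 ± 0.17. The metallothioneins Mt1 and Mt2, which bind metals, had 0.18 ± 0.15 and 0.30 ± 0.25. Cytochrome oxidase assembly genes had 0.07 ± 0.07 (Cox17), -0.07 ± 0.11 (Sco1) and -0.29 ± 0.18 (Sco2), and Steap3, a metalloreductase, had 0.56 ± 0.24 (adjusted p = 0.266). Apart from Slc31a1 and Slc11a2, no gene named here passed, over all genes or over the list alone.

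Cholesterol biosynthesis genes were lower in Ctr1-null cells as a group. Of 27 measured members, 11 fell adjusted over the list alone and 0 over all genes, with a median log2 fold change of -0.46. Among those that fell over the list alone were Srebf2, the regulator of the pathway (-0.56 ± 0.12), Sqle (-0.60 ± 0.19) and Msmo1 (-0.61 ± 0.16). Camera gave an adjusted p of 1.3e-10, and adjusted p = 0.538 with an estimated correlation. The list's mean lay at -0.74 in Ctr1-null replicate 1, -0.16 in replicate 2 and -0.30 in replicate 3, relative to the wild-type mean, and at -0.23 in wild type replicate 1. Of 17 genes of fatty acid synthesis, 5 fell and 1 rose adjusted over the list alone (median -0.19, camera adjusted p = 0.00153). It had adjusted p = 0.638 with an estimated correlation and 0.178 without Ctr1-null replicate 1. Of the 13 mRNAs encoded by mitochondrial DNA, 7 rose over the list alone and 0 over all genes (median 0.33, camera adjusted p = 1.5e-05, or adjusted p = 0.538 with an estimated correlation), among them mt-Nd5 (0.38 ± 0.10) and mt-Co2 (0.42 ± 0.11). The nuclear-encoded respiratory subunits had medians of -0.10 for complex I (camera adjusted p = 0.00617) and -0.14 for complexes III and V (camera adjusted p = 0.0121), with 0 members past the test, and adjusted p = 0.640 with an estimated correlation for each.

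Of 38 measured genes of the type I interferon response, 9 fell and 2 rose adjusted over the list alone (median -0.23, camera adjusted p = 3.9e-04). The list had adjusted p = 0.638 with an estimated correlation and 0.339 without Ctr1-null replicate 1. In that library the list's mean lay at -0.86 relative to wild type, against -0.27 and -0.15 in Ctr1-null replicates 2 and 3. Isg15 and Ifit1, further genes of the list, were also lower in wild type replicate 1 (4.68 and 16.1 CPM) than in replicate 2 (12.3 and 61.8 CPM). Camera also called the p53 target list (median -0.21, 2 of 23 lower over the list alone, adjusted p = 1.8e-05), the unfolded protein response (-0.17, 4 of 21, 2.1e-05), histone genes (-0.65, 2 of 19, 2.1e-05) and contractile genes (-0.13, 3 of 24, 0.00207) as lower. Each of these had adjusted p = 0.538 with an estimated correlation. It called ribosomal proteins (median -0.19, camera adjusted p = 2.1e-05), nucleolar genes (-0.25, 2.5e-05), ATF4 targets of the integrated stress response (-0.24, 9.3e-04) and S phase genes (-0.15, 0.00111) as lower with 0 members past the list-alone test, with adjusted p = 0.638 with an estimated correlation for ATF4 targets and 0.640 for each of the others. G2/M genes had a median of -0.06 and a camera adjusted p of 0.0390, with adjusted p = 0.675 with an estimated correlation. Wild type replicate 1 had the lowest mean of the wild type libraries in 13 of the 14 lists called lower, the exception being the unfolded protein response. Its mean was -0.45 in histone genes, against 0.28 and 0.17 in replicates 2 and 3, -0.26 in ribosomal proteins, against 0.12 and 0.15, and -0.20 in ATF4 targets, against 0.08 and 0.12. Ctr1-null replicate 1 was not below the wild-type mean in ribosomal proteins (0.05), nucleolar genes (0.08), ATF4 targets (0.04), S phase genes (2.6e-04) and G2/M genes (0.009). Ctr1-null replicates 2 and 3 lay below it in each of these lists.

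Higher as lists were NRF2 targets of the oxidative stress response, with 3 of 33 past the list-alone test (median 0.14, camera adjusted p = 0.0105, or adjusted p = 0.638 with an estimated correlation), among them Gsta4, a glutathione transferase (2.08 ± 0.41). TGF-beta targets had 6 members that rose and 3 that fell over the list alone (median 0.21, camera adjusted p = 0.0180, or adjusted p = 0.538 with an estimated correlation). Id3, a BMP and TGF-beta responsive inhibitor of transcription factors, had 0.56 ± 0.09. Camera used a preset correlation of 0.01 and called 17 of 35 lists, 3 higher and 14 lower, where an estimated correlation called 0 and fry called 0, with 21, 1 and 9 lists at an unadjusted p under 0.05. Wild type replicate 1 had the highest mean of the wild type libraries in 2 of the 3 lists called higher, NRF2 targets being the exception. Leaving out 1 library ended the call of 7 of the 17. NRF2 targets had adjusted p = 0.209 without wild type replicate 1 and 0.339 without Ctr1-null replicate 1, and TGF-beta targets 0.0537, 0.0519 and 0.0687 without wild type replicate 2, wild type replicate 3 or Ctr1-null replicate 1. G2/M genes, without wild type replicate 2, wild type replicate 3, Ctr1-null replicate 2 or Ctr1-null replicate 3, had 0.190, 0.205, 0.311 and 0.0677. The G2/M call also ended with upper-quartile factors (0.0788), library size only (0.0991) and the stricter filter (0.137), and the median ran from -0.08 to -0.01 over the scalings. Complexes III and V had 0.0572, 0.0915, 0.0876 and 0.0677, and complex I had 0.0731 without wild type replicate 3. Camera's adjusted p was 0.0544 for the MAPK pathway output list, 0.0583 for the lysosome (TFEB targets) list, 0.0641 for the copper transport and delivery list and 0.0641 for the Hox gene list. The remaining values were 0.0847 for the heat shock and proteotoxic stress list, 0.0869 for the glycolysis list, 0.102 for the fatty acid oxidation and PPAR targets list and 0.117 for the hypoxia (HIF targets) list. They were 0.123 for the zinc transporters list, 0.202 for the imprinted and developmental growth gene list, 0.210 for the antigen presentation list and 0.326 for the inflammatory and NF-kB targets list. They were 0.382 for the autophagy core list, 0.578 for the copper-dependent enzymes list, 0.586 for the iron handling list and 0.717 for the extracellular matrix and collagens list. They were 0.845 for the matrix remodelling list and 0.940 for the complex IV subunits (nuclear) list. Heat shock and proteotoxic stress (lower, adjusted p = 0.0112), MAPK pathway output (higher, 8.4e-04), extracellular matrix and collagens (higher, 0.00612), matrix remodelling (higher, 0.0463), inflammatory and NF-kB targets (higher, 0.0463) and imprinted and developmental growth genes (higher, 4.4e-07) gained a call without wild type replicate 1. That library had the lowest wild type mean in the first of these lists and the highest in the others. For imprinted genes it lay at 0.99, against -0.56 and -0.43 in replicates 2 and 3. Leaving it out widens these differences by itself, so these gains carry no support of their own. Lysosome (lower, adjusted p = 0.0214) gained a call without wild type replicate 2. Lysosome (lower, adjusted p = 0.0170) gained a call without wild type replicate 3. Glycolysis (lower, adjusted p = 0.00766), heat shock and proteotoxic stress (lower, 8.2e-04), extracellular matrix and collagens (higher, 0.0362), antigen presentation (higher, 0.00663) and Hox genes (higher, 0.0318) gained a call without Ctr1-null replicate 1. Lysosome (lower, adjusted p = 0.0490) and MAPK pathway output (higher, 0.00209) gained a call without Ctr1-null replicate 2. Copper transport and delivery (lower, adjusted p = 0.0401), zinc transporters (lower, 0.0494), lysosome (lower, 0.00969) and MAPK pathway output (higher, 0.0254) gained a call without Ctr1-null replicate 3. The 8 alternatives that kept every library gave a call to 7 of the 18 lists not called, copper transport and delivery (lowest adjusted p = 0.0137), glycolysis (0.0259), hypoxia (0.0431), heat shock and proteotoxic stress (0.0252), lysosome (0.0181), MAPK pathway output (0.0185) and Hox genes (0.0263). The median, mean and test differed in sign for zinc transporters, matrix remodelling and complex IV.

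Markers of fat cells were higher in Ctr1-null cells. All 5 measured members had positive log2 fold changes, with 1 past the test over all genes (Pparg) and 3 adjusted over the list alone (camera adjusted p = 5.0e-08, adjusted p = 0.0411 with an estimated correlation, fry adjusted p = 0.00637, over 9 lists). Lpl, a lipase of the list, was at 2.81, 0.784 and 0.744 CPM in wild type replicates 1, 2 and 3 and at 1.51, 2.27 and 4.89 in Ctr1-null, so that wild type replicate 1 lay above Ctr1-null replicates 1 and 2. In wild type replicate 1 Cebpa was at 4.93 CPM and Fabp4 at 3.29, against 0.595 and 1.84 in replicate 2 and 0.744 and 1.69 in replicate 3, while Pparg was at 19.1, 21.2 and 21.1. Among the other 8 cell type lists, camera's adjusted p was 0.0687 for the neural progenitor and glia list, 0.115 for the skeletal and cardiac muscle list and 0.335 for the macrophage and blood list. Next were 0.335 for the endothelial list, 0.619 for the fibroblast list and 0.619 for the bone and cartilage list. Last were 0.619 for the primordial germ and pluripotent list and 0.867 for the epithelial list.

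BCS in Ctr1-null cells asks what the chelator adds to loss of the importer. Cdkn1a, the cell cycle inhibitor p21, went from 229 ± 14.3 CPM (SD, n = 3) to 410.3 ± 26.1 CPM, a log2 fold change of 0.84 ± 0.08 (SE, edgeR adjusted p = 0.0117). Atf5, a stress transcription factor, rose to 91.3 ± 6.74 CPM (1.23 ± 0.12, adjusted p = 0.0117), Ddit3, the stress factor CHOP, by 0.86 ± 0.09 (adjusted p = 0.0148), Gdf15, a secreted stress cytokine, by 1.44 ± 0.17 (adjusted p = 0.0293) and Sesn2, an inhibitor of mTORC1 signalling, by 0.66 ± 0.07 (adjusted p = 0.0161). Mki67, the proliferation marker Ki-67, fell from 469 ± 12.1 CPM to 329.5 ± 4.68 CPM (-0.51 ± 0.07, adjusted p = 0.0460), and Ndnf, a secreted neurotrophic factor, fell from 42.2 ± 2.84 CPM to 14.2 ± 0.767 CPM (-1.57 ± 0.16, adjusted p = 0.0117). Zcwpw1, a histone reader, rose by 0.86 ± 0.11 (adjusted p = 0.0428). For each of these 8 genes the groups' libraries did not overlap.

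The genes lie in GRCm38 at chromosome 17, 29090976 to 29100727 for Cdkn1a, chromosome 7, 44812256 to 44816658 for Atf5, chromosome 10, 127290774 to 127296288 for Ddit3, chromosome 8, 70629393 to 70632456 for Gdf15 and chromosome 4, 132492032 to 132510501 for Sesn2. With Ccdc13 (2.16 ± 0.24, adjusted p = 0.0172) and the predicted gene Gm45140 (-0.88 ± 0.11, adjusted p = 0.0329), which the naming rule leaves out, they made up the 10 called genes, 7 higher and 3 lower. At an unadjusted p under 0.05 there were 2708 genes, and 24.3% of genes had groups that did not overlap. Chance gives 10% on average, and since genes are not independent a single split can exceed that. DESeq2 called 711. Without wild type replicate 1 edgeR called 183 genes, the same 10 among them. That library enters through the shared estimate of spread, the scaling and the filter (18835 genes tested without it), and these were not separated. A fit of only the Ctr1-null and BCS libraries, without any wild type library, called 9 genes, 6 of them among the 10. Leaving out wild type replicate 2 or 3 gave 6 and 3 called genes and Ctr1-null replicate 1 gave 1, each among the 10, while BCS replicate 2 gave 4, of which 2 were among the 10. Leaving out Ctr1-null replicate 2 or 3 or BCS replicate 1 or 3 gave 0, with 1660 to 2736 genes at an unadjusted p under 0.05.

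ATF4 targets of the integrated stress response, the program that restores amino acid supply under stress, rose with BCS. Of 39 measured members, 4 rose over all genes and 20 adjusted over the list alone, with 0 lower (median 0.40). Beside Atf5, Ddit3, Gdf15 and Sesn2 these included Trib3, a pseudokinase (1.54 ± 0.24), Atf4 (0.63 ± 0.12) and Chac1, which degrades glutathione (1.06 ± 0.28), with edgeR adjusted p of 7.5e-04, 0.00238 and 0.0111 adjusted over the list alone. Asns, asparagine synthetase, had 0.58 ± 0.26 (adjusted p = 0.0819 over the list alone). Camera gave an adjusted p of 3.0e-23, adjusted p = 0.210 with an estimated correlation, and fry 0.0455. Of 23 p53 targets, 2 rose over all genes (Cdkn1a and Sesn2) and 16 adjusted over the list alone, with 0 lower (median 0.36). Mdm2, the ubiquitin ligase of p53, had 0.65 ± 0.10, Phlda3 0.57 ± 0.10, Bax, a promoter of apoptosis, 0.30 ± 0.06 and Fas, a death receptor, 0.74 ± 0.18, while Trp53 itself had -0.14 ± 0.09. Camera gave an adjusted p of 1.6e-20, adjusted p = 0.0249 with an estimated correlation, and fry 0.00208. It was the only list of the 35 called by all of these.

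Genes of the cell cycle were lower. Of 34 G2/M genes, 1 fell over all genes (Mki67) and 10 adjusted over the list alone (median -0.21, camera adjusted p = 2.8e-12), with adjusted p = 0.394 with an estimated correlation. Plk1, a mitotic kinase, had -0.40 ± 0.07. Of 34 S phase genes, 9 fell over the list alone (median -0.26, camera adjusted p = 1.3e-10, or adjusted p = 0.510 with an estimated correlation), among them Ccne1, cyclin E1 (-0.52 ± 0.11), and the helicase subunit Mcm7 (-0.34 ± 0.08). Of 13 mitochondrially encoded mRNAs, 8 fell over the list alone (median -0.30, camera adjusted p = 4.0e-08, or adjusted p = 0.335 with an estimated correlation). The mRNA mt-Cytb had -0.46 ± 0.09 and mt-Nd2 -0.48 ± 0.10, while mt-Co1, mt-Co2 and mt-Co3 had 0.03 ± 0.14, 0.01 ± 0.11 and -0.18 ± 0.11. Chaperones and other genes of the unfolded protein response split, with 9 lower, such as Hspa5, the main chaperone of the endoplasmic reticulum (-0.41 ± 0.09), and Sdf2l1 (-0.63 ± 0.11), and 1 higher, Herpud1 (0.53 ± 0.11), over the list alone (median -0.21, camera adjusted p = 5.6e-07, or adjusted p = 0.310 with an estimated correlation).

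Contractile genes were also lower with BCS, with 1 member past the list-alone test (median -0.18, camera adjusted p = 4.2e-05, or adjusted p = 0.335 with an estimated correlation). Tpm1, a tropomyosin, had -0.41 ± 0.10. Nucleolar genes (median -0.23, camera adjusted p = 4.2e-05, or adjusted p = 0.713 with an estimated correlation), MAPK output genes (median -0.22, camera adjusted p = 0.00266, or adjusted p = 0.713 with an estimated correlation) and NF-kB targets (median -0.24, camera adjusted p = 0.00917, or adjusted p = 0.210 with an estimated correlation) were lower with 0 members past either test. Higher were HIF targets of hypoxia, with 2 over the list alone (median 0.17, camera adjusted p = 0.00449, or adjusted p = 0.306 with an estimated correlation), and lysosomal genes, with 1 (median 0.04, camera adjusted p = 0.0204, or adjusted p = 0.713 with an estimated correlation), the protease Ctsf (0.90 ± 0.20). Cholesterol biosynthesis (median 0.21, camera adjusted p = 0.00201, or adjusted p = 0.713 with an estimated correlation), fatty acid synthesis (median 0.18, camera adjusted p = 0.00559, or adjusted p = 0.713 with an estimated correlation), complex I (median 0.09, camera adjusted p = 0.00338, or adjusted p = 0.713 with an estimated correlation), autophagy (median 0.08, camera adjusted p = 0.00439, or adjusted p = 0.439 with an estimated correlation) and interferon response genes (median 0.29, camera adjusted p = 0.00749, or adjusted p = 0.713 with an estimated correlation) were higher with 0 members past the list-alone test. Without Ctr1-null replicate 1 the calls of cholesterol biosynthesis (adjusted p = 0.430), fatty acid synthesis (0.207), lysosome (0.203), MAPK (0.157), interferon (0.810) and nucleolar genes (0.360) ended. Those of cholesterol and fatty acid synthesis also ended without BCS replicate 1 (0.204 and 0.125), lysosome without BCS replicate 2 (0.0747) and nucleolar genes without BCS replicate 3 (0.0945).

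**Figure D3:**
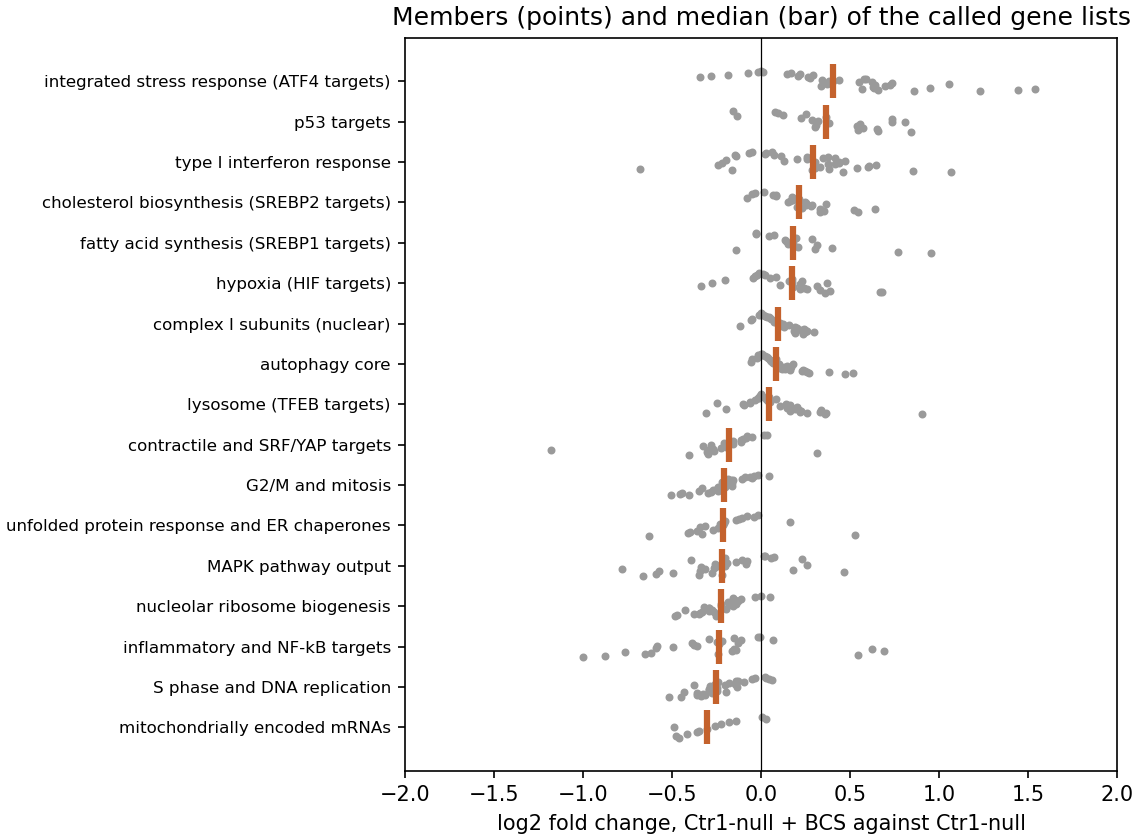
Log2 fold changes of Ctr1-null cells with BCS against Ctr1-null cells (horizontal) for the 508 list memberships of the 17 gene lists called by camera at its preset correlation (vertical), with a grey point per gene and a bar at each list's median. The medians run from 0.40 for ATF4 targets to -0.30 for mitochondrially encoded mRNAs, with 9 above and 8 below 0.

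In total camera called 17 of 35 lists with BCS, 9 higher and 8 lower, an estimated correlation called 1 and fry called 5. Camera's adjusted p reached 0.0614 for the heat shock and proteotoxic stress list, 0.0614 for the fatty acid oxidation and PPAR targets list, 0.0710 for the matrix remodelling list and 0.109 for the Hox gene list. The other values were 0.127 for the complex IV subunits (nuclear) list, 0.127 for the extracellular matrix and collagens list, 0.193 for the histone gene list and 0.228 for the oxidative stress (NRF2 targets) list. Further values were 0.233 for the glycolysis list, 0.274 for the antigen presentation list, 0.478 for the zinc transporters list and 0.589 for the iron handling list. Further values were 0.589 for the ribosomal proteins list, 0.654 for the copper-dependent enzymes list, 0.701 for the imprinted and developmental growth gene list and 0.835 for the complexes III and V subunits (nuclear) list. Further values were 0.839 for the TGF-beta targets list and 0.908 for the copper transport and delivery list. Ribosomal proteins (higher, adjusted p = 1.2e-05) gained a call without Ctr1-null replicate 1. Heat shock and proteotoxic stress (lower, adjusted p = 0.0161), extracellular matrix and collagens (higher, 0.0302) and matrix remodelling (higher, 0.0145) gained a call without Ctr1-null replicate 2. Heat shock and proteotoxic stress (lower, adjusted p = 0.00577), extracellular matrix and collagens (higher, 0.0137), matrix remodelling (higher, 0.00704) and antigen presentation (higher, 0.0137) gained a call without Ctr1-null replicate 3. Extracellular matrix and collagens (higher, adjusted p = 0.0360), matrix remodelling (higher, 0.0236) and Hox genes (higher, 0.0463) gained a call without BCS replicate 1. Heat shock and proteotoxic stress (lower, adjusted p = 0.0307) and Hox genes (higher, 0.0307) gained a call without BCS replicate 2. The 8 alternatives that kept every library gave a call to 6 of the 18 lists not called, heat shock and proteotoxic stress (lowest adjusted p = 0.0204), complex IV subunits (0.0496), fatty acid oxidation and PPAR targets (0.0249), extracellular matrix and collagens (0.0444), matrix remodelling (0.0204) and Hox genes (0.0462). The copper transport list had 0 members called; Ccs, the chaperone of superoxide dismutase, had 0.34 ± 0.12 (adjusted p = 0.230), Sco2 -0.57 ± 0.18 (adjusted p = 0.209), and Mt1 and Mt2 -0.21 ± 0.15 and -0.52 ± 0.25. Atp7a had -0.02 ± 0.08. Mean and median or test differed in sign for histone genes, iron handling and copper transport. For the 9 cell type lists, camera's adjusted p was 0.328 for the bone and cartilage list, 0.824 for the fibroblast list and 0.824 for the macrophage and blood list. It was 0.824 for the endothelial list, 0.824 for the epithelial list and 0.824 for the adipocyte list. It was also 0.824 for the neural progenitor and glia list, 0.824 for the primordial germ and pluripotent list and 0.957 for the skeletal and cardiac muscle list.

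Ctr1-null cells with BCS against wild type differ in genotype and chelator together, and here too genotype cannot be told apart from line, passage or origin. Svop, a transporter-like membrane protein, rose by 2.97 ± 0.24 (SE, edgeR adjusted p = 0.00136), Prelp, a matrix proteoglycan, by 3.43 ± 0.56 (adjusted p = 0.00769) and Des, the muscle filament desmin, by 2.68 ± 0.47 (adjusted p = 0.00952). Fat cell genes rose, Pparg by 1.24 ± 0.15 (adjusted p = 0.00462) and Fabp4 by 2.15 ± 0.29 (adjusted p = 0.00560). Cxcl10 fell from 37.9 ± 20.8 CPM (SD, n = 3) to 4.77 ± 0.473 CPM (-2.99 ± 0.46, adjusted p = 0.00663), Runx3, a transcription factor, from 8.81 ± 5.69 CPM to 1.42 ± 0.299 CPM (-2.63 ± 0.53), and Erfe, which encodes the iron regulator erythroferrone, from 14.3 ± 6.30 CPM to 2.76 ± 0.169 CPM (-2.37 ± 0.35, adjusted p = 0.00604). The other large rises were Islr (4.45, 95% interval 2.03 to 6.87), C1s1 (4.06 ± 0.81), Igdcc4 (3.35 ± 0.53), Kcp (2.96 ± 0.81), Mst1 (2.91 ± 0.36), Col10a1 (2.69 ± 0.60) and Efs (2.65 ± 0.53). The other large falls, with Slc31a1, were Tmem176b (-2.36 ± 0.42), Msln (-2.30 ± 0.37), Cgn (-2.14 ± 0.53), Tmem176a (-2.13 ± 0.37), Lrp2 (-1.95 ± 0.34) and F2rl1 (-1.83 ± 0.32). Without wild type replicate 1 the log2 fold changes were 6.58 for Islr, 4.86 for C1s1, 4.13 for Igdcc4, 4.45 for Kcp, 3.98 for Col10a1 and 3.59 for Efs, and those of Islr and Kcp were 3.74 and 2.22 without BCS replicate 3. Islr lost its call without wild type replicate 2 (adjusted p = 0.0936), wild type replicate 3 (0.0944), BCS replicate 1 (0.0564) or BCS replicate 3 (0.0932). C1s1 lost its call without wild type replicate 2 (adjusted p = 0.0618), wild type replicate 3 (0.0673) or BCS replicate 3 (0.0545). Kcp lost its call without wild type replicate 2 (adjusted p = 0.123), wild type replicate 3 (0.132), Ctr1-null replicate 2 (0.0595), BCS replicate 1 (0.0781) or BCS replicate 3 (0.146). Col10a1 lost its call without wild type replicate 2 (adjusted p = 0.0717), wild type replicate 3 (0.0703), BCS replicate 1 (0.0536) or BCS replicate 3 (0.0772). Efs lost its call without wild type replicate 2 (adjusted p = 0.0607), wild type replicate 3 (0.0599) or BCS replicate 3 (0.0605). Runx3 lost its call without wild type replicate 2 (adjusted p = 0.0568), wild type replicate 3 (0.0608), BCS replicate 1 (0.0576) or BCS replicate 3 (0.0701). Cgn lost its call without wild type replicate 2 (adjusted p = 0.0894), wild type replicate 3 (0.104), BCS replicate 1 (0.0921), BCS replicate 2 (0.0568) or BCS replicate 3 (0.112).

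The test called 2916 genes, 1576 higher and 1340 lower, of which 709 and 148 changed by at least 2-fold. With library size alone the median log2 fold change of all genes was 0.11, against 0.01 with TMM, and 2064 genes were higher and 784 lower. Without wild type replicate 1 there were 5840 called genes, 2811 of them among the 2916. Here too, leaving out the library that differs narrows the wild type spread. Without wild type replicate 2 or 3 or BCS replicate 1 or 3 there were 645, 568, 796 and 640.

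Against wild type, 20 of 34 S phase genes and 15 of 34 G2/M genes fell over all genes, and 23 and 20 adjusted over the list alone, where 1 G2/M gene rose. The S phase list (median -0.42, camera adjusted p = 8.4e-11, or adjusted p = 0.640 with an estimated correlation) included Ccne1 (-0.74 ± 0.12), and the G2/M list (median -0.31, camera adjusted p = 9.5e-10, or adjusted p = 0.640 with an estimated correlation) included Plk1 (-0.51 ± 0.07). Of 21 genes of the unfolded protein response, 14 fell over all genes and 16 over the list alone (median -0.37, camera adjusted p = 1.6e-10, or adjusted p = 0.428 with an estimated correlation), such as Hspa5 (-0.67 ± 0.09) and Dnajc3 (-0.50 ± 0.07). Contractile genes had 9 and 11 of 24 lower (median -0.29, camera adjusted p = 6.9e-07, or adjusted p = 0.491 with an estimated correlation), with Vcl, vinculin, at -0.71 ± 0.09 and Flna, filamin A, at -0.82 ± 0.11. Nucleolar genes had 6 and 18 of 31 (median -0.45, camera adjusted p = 6.0e-09, or adjusted p = 0.647 with an estimated correlation), histone genes 5 and 11 of 19 (median -0.76, camera adjusted p = 1.0e-04, or adjusted p = 0.640 with an estimated correlation), and cholesterol biosynthesis genes 3 and 3 of 27 (median -0.24, camera adjusted p = 0.0191, or adjusted p = 0.834 with an estimated correlation). Heat shock genes had 4 lower over all genes, and 9 lower and 2 higher over the list alone (median -0.34, camera adjusted p = 0.0191, or adjusted p = 0.769 with an estimated correlation). Ribosomal proteins had 2 of 53 lower over all genes and 0 over the list alone (median -0.14, camera adjusted p = 0.0151, or adjusted p = 0.834 with an estimated correlation). Rps12, which like other ribosomal proteins has pseudogenes of similar sequence, had -0.70 ± 0.19 and passed over all genes but not over the list alone (adjusted p = 0.177). Rps12 lost its call without wild type replicate 2 (adjusted p = 0.106), wild type replicate 3 (0.137), Ctr1-null replicate 2 (0.0556), BCS replicate 1 (0.0987) or BCS replicate 3 (0.128).

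Higher against wild type were ATF4 targets, 12 of 39 over all genes with 1 lower, and 15 and 2 over the list alone (median 0.19, camera adjusted p = 1.9e-04, or adjusted p = 0.647 with an estimated correlation); Atf5 had 1.34 ± 0.12 and Gdf15 1.65 ± 0.18. Of 23 p53 targets 4 rose over all genes, and 7 rose and 2 fell over the list alone (median 0.18, camera adjusted p = 0.0151, or adjusted p = 0.640 with an estimated correlation), with Cdkn1a at 0.70 ± 0.08 and Mdm2 at 0.64 ± 0.10. Genes of fatty acid oxidation had 7 of 23 higher over all genes, and 9 higher and 1 lower over the list alone (median 0.16, camera adjusted p = 0.0191, or adjusted p = 0.428 with an estimated correlation), with Acadvl, an acyl-CoA dehydrogenase, at 0.51 ± 0.06 and Pdk4, which restrains glucose oxidation, at 1.02 ± 0.16. Hox genes had 4 of 18 higher by both counts (median 0.32, camera adjusted p = 0.0191, or adjusted p = 0.647 with an estimated correlation), such as Hoxd12 (0.96 ± 0.19). Hoxd12 lost its call without wild type replicate 2 (adjusted p = 0.0577) or wild type replicate 3 (0.0608). Without wild type replicate 1 the calls of ATF4 targets (adjusted p = 0.158), p53 targets (0.159), fatty acid oxidation (0.122) and Hox genes (0.0745) ended. The omission of wild type replicate 2 or 3 ended those of heat shock (0.0564 and 0.0726), cholesterol (0.0916 and 0.0911) and ribosomal protein genes (0.128 and 0.212). The stricter filter on low counts also ended these 3 (0.0549, 0.0721 and 0.0591), and the authors' factors in edgeR that of fatty acid oxidation (0.0589). Without BCS replicate 2 those of cholesterol (0.208) and p53 targets (0.0594) ended, and without BCS replicate 3 that of Hox genes (0.0910). Over the scalings the median ran from 0.04 to 0.26 for fatty acid oxidation, 0.12 to 0.30 for ATF4 targets and 0.15 to 0.28 for p53 targets. It ran from -0.16 to -0.04 for ribosomal proteins and -0.28 to -0.14 for cholesterol biosynthesis.

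Wild type replicate 1 had the lowest mean of the wild type libraries in 8 of the 9 lists called lower, the unfolded protein response being the exception, and the highest in 2 of the 4 called higher, fatty acid oxidation and Hox genes. Camera called 13 of 35 lists against wild type, 4 higher and 9 lower, an estimated correlation called 0 and fry called 6, with 15, 3 and 13 lists at an unadjusted p under 0.05. Lists that camera did not call had an adjusted p of 0.0592 for the glycolysis list, 0.0964 for the TGF-beta targets list, 0.145 for the complexes III and V subunits (nuclear) list and 0.145 for the zinc transporters list. These were followed by 0.145 for the antigen presentation list, 0.273 for the copper transport and delivery list, 0.273 for the autophagy core list and 0.273 for the extracellular matrix and collagens list. Next came 0.375 for the oxidative stress (NRF2 targets) list, 0.375 for the matrix remodelling list, 0.418 for the inflammatory and NF-kB targets list and 0.434 for the complex IV subunits (nuclear) list. The last were 0.479 for the iron handling list, 0.479 for the type I interferon response list, 0.491 for the copper-dependent enzymes list and 0.491 for the hypoxia (HIF targets) list. The last were 0.534 for the imprinted and developmental growth gene list, 0.600 for the MAPK pathway output list, 0.674 for the fatty acid synthesis (SREBP1 targets) list and 0.808 for the mitochondrially encoded mRNA list. The last were 0.892 for the lysosome (TFEB targets) list and 0.981 for the complex I subunits (nuclear) list. Complexes III and V subunits (lower, adjusted p = 0.00970), extracellular matrix and collagens (higher, 0.00487), matrix remodelling (higher, 0.00820), TGF-beta targets (higher, 0.0162) and imprinted and developmental growth genes (higher, 1.4e-04) gained a call without wild type replicate 1. That library had the lowest wild type mean in the first of these lists and the highest in the others. Leaving it out widens these differences by itself. Glycolysis (lower, adjusted p = 0.0372) and antigen presentation (higher, 0.0450) gained a call without Ctr1-null replicate 1. Glycolysis (lower, adjusted p = 0.0470) gained a call without BCS replicate 1. The 8 alternatives that kept every library gave a call to 5 of the 22 lists not called, glycolysis (lowest adjusted p = 0.00877), complexes III and V subunits (0.0344), zinc transporters (0.0497), TGF-beta targets (0.0252) and antigen presentation (0.0385). In the copper transport list 5 of 27 genes fell over all genes: Slc31a1, Slc11a2 (-0.52 ± 0.09), Sco2 (-0.86 ± 0.18, adjusted p = 0.0163), Steap1 (-0.53 ± 0.12) and Atp7a (-0.30 ± 0.08). Of 16 copper-dependent enzymes, 3 fell and 0 rose, among them Sod3, extracellular superoxide dismutase (-0.87 ± 0.19), and Loxl4, a lysyl oxidase (-0.60 ± 0.16). Over all 18408 genes tested, 2916 were called in this comparison, 1340 of them lower, and Slc31a1 is the targeted gene itself. Camera called neither list (adjusted p = 0.273 and 0.491), so these counts do not mark a response of copper genes as a group. Slc11a2 lost its call without wild type replicate 3 (adjusted p = 0.0537). Sco2 lost its call without wild type replicate 3 (adjusted p = 0.0617), BCS replicate 1 (0.0669) or BCS replicate 3 (0.0708). Steap1 lost its call without wild type replicate 2 (adjusted p = 0.0714), wild type replicate 3 (0.0520), BCS replicate 1 (0.0780) or BCS replicate 3 (0.0600). Atp7a lost its call without wild type replicate 2 (adjusted p = 0.113), wild type replicate 3 (0.113), Ctr1-null replicate 2 (0.0583), BCS replicate 1 (0.123), BCS replicate 2 (0.0825) or BCS replicate 3 (0.0885). Sod3 lost its call without BCS replicate 1 (adjusted p = 0.0626) or BCS replicate 3 (0.0656). Loxl4 lost its call without wild type replicate 2 (adjusted p = 0.127), wild type replicate 3 (0.143), Ctr1-null replicate 2 (0.0593), BCS replicate 1 (0.0991), BCS replicate 2 (0.0608) or BCS replicate 3 (0.143). The fat cell list had 3 of 5 higher by both counts (camera adjusted p = 1.0e-04, or adjusted p = 0.154 with an estimated correlation). For the other 8 cell type lists it was 0.269 for the macrophage and blood list, 0.269 for the endothelial list and 0.269 for the skeletal and cardiac muscle list. Then it was 0.269 for the bone and cartilage list, 0.408 for the neural progenitor and glia list and 0.408 for the primordial germ and pluripotent list. Finally it was 0.870 for the fibroblast list and 0.870 for the epithelial list. Medians, means and tests differed in sign for MAPK output, fatty acid synthesis, iron handling, hypoxia, lysosome and complex I, each of them without a call.

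The last comparison asks whether the change with genotype and the change with BCS run the same way. Across 18408 genes, which are not independent replicates, their log2 fold changes had r = -0.0433 (Spearman's rho 0.0147). Both use the Ctr1-null libraries, and 100 simulated sets without any effect gave r = -0.495 (range -0.520 to -0.466). The simulation drew each gene and library independently, so its range leaves out shifts that many genes share. It therefore does not show how far r can vary between libraries like these. The covariance was -0.00748 against a simulated -0.0436, a difference of 0.0361. Calls overlapped in 0 genes, with 2 and 10 called, and independent lists would share 3.8e-04 of a gene among higher and 1.6e-04 among lower calls. Of the 10 genes called with BCS, Ccdc13, Zcwpw1, Gdf15 and Atf5 had the same sign in both steps. Ccdc13 had log2 fold changes of 1.22 and 2.16, and Gdf15 of 0.21 and 1.44. Cdkn1a, Ddit3, Sesn2, Mki67, Ndnf and Gm45140 had opposite signs. Cdkn1a had -0.15 ± 0.08 in the first step and 0.84 ± 0.08 in the second, and Sesn2 -0.23 ± 0.07 and 0.66 ± 0.07. Pparg, called in the first step, had 1.37 ± 0.15 and -0.13 ± 0.15.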

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

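The authors' factors in edgeR and DESeq2 and the robust fit were chosen after the data were seen. For Ctr1-null against wild type, 2 genes were called, and the count was 4 with DESeq2 size factors in edgeR (RLE), upper-quartile factors, library size only, the stricter filter on low counts, the authors' factors in edgeR and the robust quasi-likelihood fit. It was 265 with no filter on low counts, 1056 with the DESeq2 test, 855 with the authors' factors in DESeq2, 6 with limma-voom, and 1 with only the 2 groups compared and with the replicate block. For BCS against Ctr1-null, 10 genes were called, 114 with no filter, 711 with the DESeq2 test and 588 with the authors' factors in DESeq2. It was 9 with only the 2 groups compared, 2 with the replicate block and 4 at the 2-fold threshold. For BCS against wild type, 2916 were called, 4081 with the DESeq2 test, 3632 with the authors' factors in DESeq2, 1543 with the replicate block and 857 at the 2-fold threshold. Leaving out 1 library gave 1 to 3254, 0 to 183 and 568 to 5840 genes in these comparisons, the highest each time without wild type replicate 1. The cause of these differences between tools was not tested. The replicate numbers showed no clear pairing of the libraries: 2 of 9 same-number pairs had deviations with r over 0.1 (r from -0.319 to 0.275), and 1 of 9 samples was closest to its own number. With 3 libraries per group this cannot exclude a pairing, and the labels do not say what the number marks.

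Lists called fell from 17 to 0 (Ctr1-null against wild type), 17 to 1 (BCS against Ctr1-null) and 13 to 0 (BCS against wild type) for camera with an estimated correlation, and to 0, 5 and 6 for fry in place of camera. The correlation of the genotype and chelator changes was 0.0795 with the stricter filter, 0.112 over genes called in at least 1 of the comparisons and -0.218 to 0.00887 on leaving out 1 library. No value without an effect was simulated for these, and choosing called genes depends on the changes themselves, so they cannot be read beside the value over all genes. Slc31a1 kept its direction and call against wild type in all 21 alternatives of both comparisons. Between BCS and Ctr1-null, where it was not called, its log2 fold change was 0.00193 with limma-voom, 0.34 without Ctr1-null replicate 2 and 0.14 without BCS replicate 3, and -0.37 to 0.34 on leaving out 1 library. Its Ctr1-null counts of 68 to 200 limit this value. Of the called named genes other than Slc31a1, 0 of 1, 0 of 8 and 41 of 111 stayed called in all 21 alternatives, and 0 changed direction.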

Other observations

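The tests chosen after the result was seen are those on Slc31a1 in wild type replicate 1, on scaling, on p53 targets shared with the ATF4 program, on fat cell markers, on single wild type libraries and on other splits of the samples; those on depth and on GC content were written before. Imprinted and growth genes were among those that set wild type replicate 1 apart, and the genes given here were picked after their values were seen. Rian, a noncoding RNA of the Meg3 locus, was at 38.4, 2.51 and 2.31 CPM in wild type replicates 1, 2 and 3. H19 was at 146, 26.1 and 26.1 CPM and Col15a1, a collagen, at 15.8, 0.486 and 0.372 CPM. The means of the imprinted list lay at 0.99, -0.56 and -0.43 relative to the wild-type mean in replicates 1, 2 and 3. Other lists split these libraries in the same way, such as fat cell markers (0.74, -0.36 and -0.38) and fibroblast markers (0.61, -0.30 and -0.32). Whether the imprinted list stands out from them was not tested. Ifit1, an interferon-induced gene, was at 16.1, 61.8 and 54.7 CPM.

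Wild type replicate 1 stood apart from replicates 2 and 3. Its Slc31a1 level was 102% of their mean, which argues against Ctr1-null cells or RNA in that library. After thinning to equal totals it still differed by over 2-fold in 1485 and 1554 genes, against 298 between replicates 2 and 3, and GC content with transcript length held 0.671% of the variance, which argue against depth and base composition as the whole cause. Its difference from 1 wild type library correlated across 18408 genes, which are not independent, with that of Ctr1-null from the other one (r = 0.613 and 0.621). Culture state, passage and origin of these cells stay open; no biological explanation was tested, and the labels give no batch.

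ATF4 and p53 targets rose with BCS in Ctr1-null cells by camera at its preset correlation. The ATF4 call is lost with an estimated one (adjusted p = 0.210) and the p53 call holds (adjusted p = 0.0249). Both lists lay lower in Ctr1-null than in wild type cells (medians -0.24 and -0.21). In BCS cells against wild type their medians were 0.12 to 0.30 and 0.15 to 0.28 over the scalings. Both of those calls ended without wild type replicate 1 (camera adjusted p = 0.158 and 0.159). With BCS against Ctr1-null, the lower of the ATF4 and p53 medians was at least 0.35 under 5 scalings. These scalings moved the median of all genes only between -0.0089 and 0.049. They could not have removed a rise of this size, so this test draws no conclusion on scaling. The lower median was 0.36 after removing a trend on GC content and length, which argues against base composition as the whole cause. Without 7 members set down as ATF4 or CHOP targets, the p53 list kept 16 genes with a median of 0.35 and a camera p of 8.3e-15 (p = 0.00161 with an estimated correlation), which argues against shared ATF4 targets as the whole cause. SV40 T antigen binds p53, so what these targets report in such cells is open. Copper removal and other effects of BCS both stay open, since no wild type cells received it and neither was tested.

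Fat cell genes were higher in Ctr1-null than in wild type cells. Adipoq, Plin1, Cidec and Cfd, abundant in mature fat cells, together made 3.01% of the Fabp4 counts of the Ctr1-null libraries (43 against 1428), which argues against mature adipocytes in these cultures. Pparg kept a log2 fold change of at least 1.32 without any 1 wild type library. Its wild type values of 19.1, 21.2 and 21.1 CPM lie so close that this could not have come out otherwise. Ctr1-null replicate 1 was the highest, at 66.95 CPM against 43.04 and 48.48, and the lowest log2 fold change over 21 alternatives was 1.16. Its call ended without wild type replicate 2 or 3 (edgeR adjusted p = 0.266 and 0.310, in a range of 1.1e-12 to 0.310 over the alternatives). The call ended in 8 of the 21 alternatives. Loss of Ctr1 and a difference between the cell lines in origin or passage both stay open and were not tested.

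The 6 libraries of a comparison make 10 splits, too few for a share under 0.05. For Ctr1-null against wild type, 3 splits called as many genes as the real one (2), with 2349 the highest other, and 3 as many lists (17), with the others from 12 to 19. The split with 2349 sets wild type replicate 1 and Ctr1-null replicates 2 and 3 against the rest, which points to a structure of the samples beside genotype. For BCS against Ctr1-null, 1 split called as many genes (10, highest other 0) and 3 as many lists (17, others from 10 to 21). For BCS against wild type these were 1 (2916, highest other 0) and 7 (13, others from 9 to 18). Splits that mix the groups also called many lists. The number of lists called by camera at its preset correlation therefore does not set the real groups apart.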
